A study of Mus musculus with 18 samples.

How the data were processed

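The deposited series table holds 115125 transcript entries for 18 libraries, and its values are expected or estimated counts, per the file headers, which carry GENCODE transcript and gene names. All 18 value columns were used. Estimated counts were summed over the transcripts of each gene identifier, giving 47643 genes, and rounded to whole numbers before testing. 118 gene names are shared by 244 identifiers, which were kept apart and named together only where their values are equal. 92 entries are ERCC spike-in sequences, which the labels do not mention, and these were kept out of library totals and tests. Per the submitters' processing notes bcl2fastq 2.16.0.10 and the mm10 build were used. The aligner, the quantifier and the strand of counting are not given in the sources used here. Per the labels' protocols the RT-RamDA libraries began from 10 pg of total RNA and had 17 cycles of PCR with a single-stranded DNA kit, and the bulk libraries began from 200 ng, were depleted of rRNA with RNase H and had 7 cycles. The series text counts 12 RT-RamDA samples while 15 are listed, and all 15 were analysed.

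Input amount, kit, rRNA depletion and PCR cycles all differ between RT-RamDA and bulk, so the bulk comparisons measure the sum of these. Replicate numbers were not treated as pairs in the chosen model, since genewise residuals of libraries with the same number correlated between -0.034 and 0.036 over 7819 genes and 3 of 18 libraries matched best with their own number.

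Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test) with BH adjustment over all tested genes, called at an adjusted p under 0.05, two-sided. Random primers against dT, NSR against N6, dT added against not, and the interaction of NSR with dT are contrasts in a fit of the 15 RT-RamDA libraries, and each primer set against bulk was fitted on its own 6 libraries. Square roots of the common dispersion were 0.82 for the 15 libraries and 0.44, 0.48, 0.69, 0.43 and 0.47 for N6, NSR, dT, N6dT and NSRdT with bulk. A fold change is given as "at least" where all libraries of a side have 0 counts, with 3 counts per library as the floor. CPM beside a log2 fold change are TMM-scaled and SDs are over libraries, while CPM of histone families, of mitochondrial genes with their copies and of bulk replicates are of library totals.

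23 gene lists were fixed before the data were examined: rRNA-annotated loci, mitochondrial rRNAs, mRNAs and tRNAs, replication-dependent histones, small RNAs without poly(A), snoRNAs and scaRNAs, long non-coding RNAs, cytoplasmic ribosomal proteins, nuclear oxidative phosphorylation, translation factors, very long transcripts, pluripotency, naive pluripotency, DNA methylation and chromatin, cell cycle, glycolysis, and markers of 2-cell-like cells, primitive endoderm, mesendoderm, neuroectoderm, fibroblast feeders and trophectoderm. The 2-cell-like list was tested in the RT-RamDA comparisons only. Each list was tested with camera (limma 3.58.1, voom, preset correlation of 0.01), adjusted over all lists and comparisons, with an estimated correlation and fry as alternatives, and its calls were also adjusted over the list alone.

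Genes named in the text come from a rule fixed before the data were examined: up to 8 higher and 8 lower genes by log2 fold change among called genes with a mean log2 CPM of 5 or more and no overlap between sides, leaving out predicted symbols and processed pseudogenes named by number, then from each list the 2 most abundant and the 2 with the smallest p, and always Pou5f1, Nanog, Sox2, Actb, Gapdh, Malat1, Neat1, Rn7sk and Rmrp. The interaction did not require the sides to be apart, and all of its called genes are named. Called members of lists with 5 or fewer calls on a side, and Tnf and Igkv1-110, were added after their values were seen. Not every gene the rule allows is printed. Reads can be shared between near-identical genes, so single histones, Rps12, Ftl1, Rpl39-ps, Eno1b, the U3 genes, Rn7s1 and Rn7s2, and mitochondrial genes with nuclear copies are uncertain as genes.

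Library measures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1: detected genes with 1 count or more after thinning each library to 5333302 counts, shares of estimated counts, and the Spearman correlation with the mean of bulk over 16151 genes at 1 CPM or more there. Group means were compared by exact permutation tests, two-sided, in strata only for NSR against N6 and added dT, BH adjusted over 20 tests. Replicate spread is the median coefficient of variation (CV) over 9311 genes at 10 CPM or more in bulk, 0.315 with N6, 0.322 with NSR, 0.391 with dT, 0.302 with N6dT, 0.298 with NSRdT and 0.0761 in bulk (0.0435 without bulk replicate 2). Figures were drawn with matplotlib 3.10.9. Shared sequence was measured as shared 31-mers between GENCODE vM21 transcripts, and lengths are those of each gene's transcript with the largest mean estimate.

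Alternatives fixed before the data were examined were library totals alone as scaling, DESeq2's median-ratio size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, rRNA-annotated and mitochondrial genes removed, a replicate block, other sets of libraries in the fit and each library left out. The rRNA share with 4 further loci (Lars2, Mir6236, AA474408 and Gm15662), mitochondrial mRNAs with 5 near-identical copies, and mitochondrial genes summed with their chromosome 1 copies, and then with Rps12 and mt-Nd3 summed with theirs as well, were added after seeing the data. In negative binomial counts simulated from the real means and dispersions with 200 genes changed, the random against dT fit recovered 11.9% of 2-fold, 53.7% of 4-fold and 83.3% of 8-fold changes with 6.6% false calls, and the N6 against bulk fit 9.0%, 65.7% and 84.8% with 2.8% false calls. The calls of 1 gene are not reported here.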

Results

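RNA from mouse 5G6GR embryonic stem (ES) cells, a line known for an inducible Gata6 fusion and grown here without feeders, was measured in 18 libraries, all from purified total RNA. For 15 of them the RNA was diluted to 10 pg and copied by RT-RamDA, in which cDNA strands are displaced and made again along the template during reverse transcription. Each of 5 primer sets was used for 3 libraries: random hexamers (N6), not-so-random primers (NSR), which were designed to avoid ribosomal RNA (rRNA), oligo(dT) (dT), which anneals to poly(A) tails, and dT mixed with N6 (N6dT) or with NSR (NSRdT). The other 3 libraries (bulk) came from 200 ng of RNA depleted of rRNA. Estimated counts per library ranged from 5362297 to 10326614. Nothing in the labels says that libraries of a group came from separate cultures, so each p-value here measures spread between libraries, which for diluted RNA may be technical only. Values after gene names are log2 fold changes with their standard errors (SE), n is 3 libraries per group, and "adjusted p" for a gene is that of the edgeR quasi-likelihood F test with Benjamini-Hochberg (BH) adjustment, called under 0.05. Counts are PCR reads without molecular identifiers, so errors that treat them as independent molecules are too small.

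The primer set changed which kinds of RNA filled a library. Loci annotated as rRNA took 53.0% ± 0.374 (SD) of estimated counts with N6, 43.5% ± 0.583 with NSR and 7.21% ± 0.169 with dT, against 10.4% ± 0.253 in bulk. NSR lowered this share by 11.3 percentage points against N6 (libraries with and without dT together; exact permutation test, two-sided, n = 6 against 6, p = 0.005, adjusted p = 0.01, the smallest p these permutations can give). With 4 rRNA-like loci added (Lars2, Mir6236, AA474408 and Gm15662, chosen after seeing the data), dT stood above bulk, at 23.7% ± 0.72 against 10.4% ± 0.253, and Lars2 alone took 15.9% with dT. Genes encoded in mitochondrial DNA took 13.3% with N6, 15.6% with NSR, 9.33% with dT and 2.42% in bulk, a gap of 10.8 points between RT-RamDA and bulk (same kind of test, as for every p in this paragraph, n = 15 against 3, p = 0.001225, again the smallest possible, adjusted p = 0.006127). Bulk RNA was depleted of rRNA, and with mitochondrial mRNAs only that gap was 0.0360 points and not called (adjusted p = 0.928). By that measure dT stood above random primers (3.37% against 1.595% with N6 and 1.91% with NSR) and libraries with added dT 0.889 points above those without. With 5 near-identical copies counted in, a choice made after the data were seen, these became 3.43% against 2.30% and 2.71%, and 0.203 points (adjusted p = 0.0412), so most of the 0.889 lay in reads held by copies. Replication-dependent histones, whose mRNAs end in a stem-loop without a poly(A) tail, took 0.262% with N6, 0.248% with NSR, 0.0474% with dT and 1.30% in bulk. Cytoplasmic ribosomal protein mRNAs made up 0.979% with N6, 1.23% with NSR, 6.90% with dT, 1.89% with N6dT, 2.55% with NSRdT and 5.02% in bulk. In libraries thinned to equal depth 17307 ± 117 genes were detected with N6, 17828 ± 308 with NSR, 15549 ± 238 with dT, 17830 ± 91.2 with N6dT, 18235 ± 43.4 with NSRdT and 23616 ± 250 in bulk. dT alone differed from random primers alone by -2018 detected genes (exact permutation test, n = 3 against 6, p = 0.0119, the smallest possible, adjusted p = 0.01488). NSR gave 463 more than N6 and added dT 465 more than none (exact permutation tests, n = 6 against 6, p = 0.005 and adjusted p = 0.01 for each). Thinned after removing rRNA-annotated and mitochondrial genes, the NSR difference was 121 and not called (adjusted p = 0.335). Without thinning neither was called (394 and 410, adjusted p = 0.05 and 0.0588). RT-RamDA differed from bulk by -6266 (exact permutation test, n = 15 against 3, p = 0.001225, adjusted p = 0.006127). Rank correlation with the bulk mean was 0.879 with N6, 0.876 with NSR, 0.838 with dT, 0.894 with N6dT and 0.892 with NSRdT, and added dT raised it by 0.0154 (p = 0.005, adjusted p = 0.01). With nuclear rRNA loci only, the rRNA-annotated share of RT-RamDA was 16.5 points above bulk and was not called, against 27.3 points and adjusted p = 0.02884 with all loci (n = 15 against 3).

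**Figure D1:**
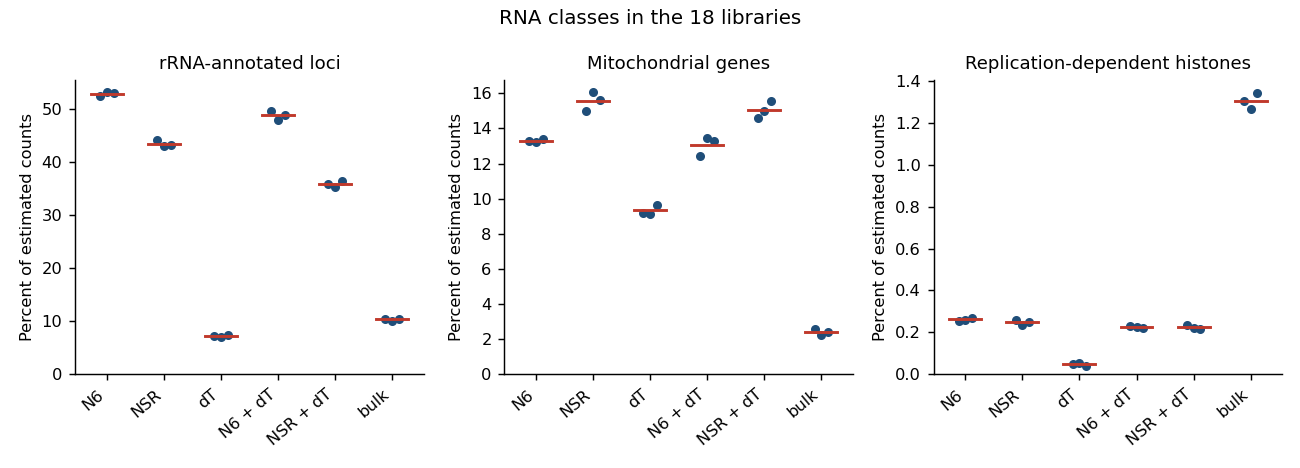
Percent of estimated counts in rRNA-annotated loci, in genes of mitochondrial DNA and in replication-dependent histones for the 6 groups. Each point is a library (18 in all, 3 per group) and each red line is the group mean.

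Random primers alone (N6 and NSR, n = 6) against dT alone (n = 3) separated RNAs by poly(A) tail and by length. Of 63 measured replication-dependent histones 51 were higher with random primers, 1 was lower (Hist1h2ap, -0.60, chosen after its values were seen) and 11 were not called (54 and 1 adjusted over the list alone). Their median was 4.73, or 4.51 with the 11 genes absent from dT set at their bound. Histone reads are shared between near-identical genes, so family sums are firmer. H1 mRNAs stood at 732 ± 38 CPM (of library totals, SD) with N6, 626 ± 28 with NSR and 43.3 ± 5.9 with dT. H2B mRNAs gave 859 ± 43, 770 and 55.2 ± 17, and H2A 472 ± 16, 417 ± 52 and 319 ± 23, the last mostly Hist1h2ap. The H2B gene Hist2h2bb was at least 439-fold higher and the H2A gene Hist1h2ai at least 351-fold, both with no count in dT. Hist1h2bg stood at 8.97 ± 0.64 and the linker histone Hist1h1c at 6.15 ± 0.28. Small RNAs that end without poly(A) were higher for 9 of 20 and lower for none (13 and 0 adjusted over the list alone). Rpph1, the RNA of RNase P, stood at 11.37 ± 0.50 (552 ± 140 CPM against 0.193 ± 0.28). Rn7sk, which restrains the elongation factor P-TEFb, stood at 4.10 ± 0.09 and Rmrp, of RNase MRP, at 5.95 ± 0.19. Of 36 snoRNAs and scaRNAs, which guide RNA modification, 11 were higher (Scarna10 by at least 58.6-fold) and 1 lower (Snord47, -4.95, not called without 7 of the 9 libraries), or 12 and 1 adjusted over the list alone. Both calls of these small RNA lists were lost, with adjusted p = 0.284 with an estimated correlation for the small RNAs and adjusted p = 0.0835 with an estimated correlation for the snoRNAs. Malat1, a nuclear long non-coding RNA that ends in a triple helix without poly(A), stood at 6.93 ± 0.22 (3920 ± 180 against 32.1 ± 12 CPM), and Neat1, the scaffold of paraspeckles, at 2.20 ± 0.20. The list of 38 long non-coding RNAs had 9 higher and 5 lower (13 and 7 adjusted over the list alone). The lower ones were Gas5, Snhg1, Snhg5, Snhg6 and Epb41l4aos, all hosts of snoRNAs. Its median of 0.38 became -0.55 by library totals alone.

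mRNAs of the ribosome went the other way. Of 83 cytoplasmic ribosomal protein genes none was higher and 81 were lower with random primers (the same adjusted over the list alone), with a median of -1.78 (camera, adjusted p = 3.6e-99). Rps29 stood at -4.85 ± 0.22 (17.3 ± 6 against 498 ± 5.5 CPM), Rplp2 at -4.30 ± 0.13 and Rpl4 at -0.74 ± 0.06. Nuclear genes of oxidative phosphorylation were lower for 61 of 69 and higher for none (66 adjusted over the list alone; median -2.07, adjusted p = 2.66e-41). Among them were Atp5g3 (-3.05 ± 0.18) and Cox8a (-3.08 ± 0.21). Of 30 translation factors 15 were lower and 1, the long scaffold mRNA Eif4g1 (1.21), was higher (18 and 2 adjusted over the list alone). Eef1a1 stood at -0.62 ± 0.04 and Eef1b2 at -1.69 ± 0.10. Very long transcripts did the opposite, with 60 of 76 higher and none lower (65 adjusted over the list alone; median 1.44, adjusted p = 2.03e-25). They include the ubiquitin ligase Huwe1 (1.86 ± 0.14), the deubiquitinase Usp9x (1.36 ± 0.12) and the splicing coactivator Srrm2 (2.87 ± 0.12; 471 ± 29 against 64.3 ± 2.9 CPM). Over 11601 protein-coding genes the log2 fold change rose with the length of the gene's most abundant transcript (rank correlation 0.46), from a median of -1.40 at 500 to 1000 bp to 1.20 above 8000 bp. The 148 genes under 500 bp broke this trend, with a median of 0.17.

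**Figure D2:**
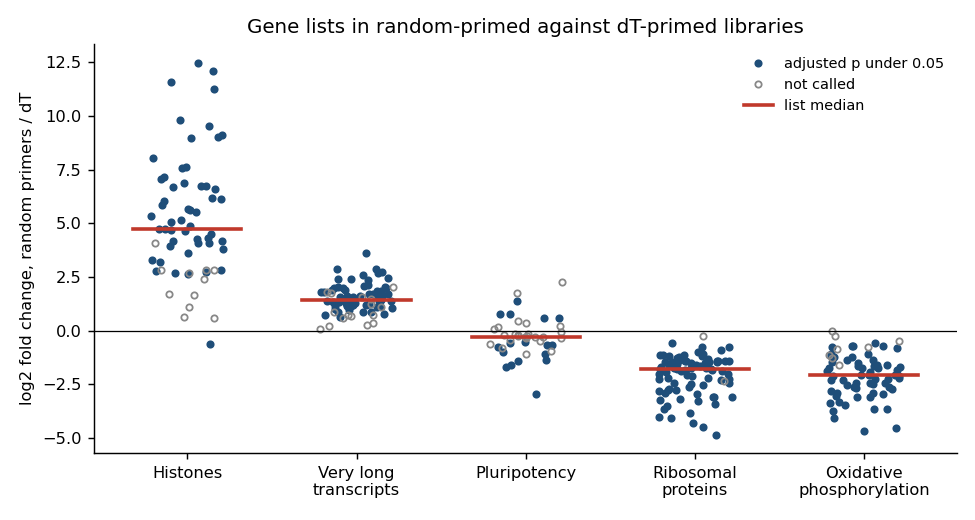
Log2 fold change of random primers (n = 6 libraries) against dT (n = 3) for genes of 5 fixed lists. Filled points are called at an adjusted p under 0.05, open points are not, and red lines are list medians (4.73 for histones, -1.78 for ribosomal proteins).

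**Figure D3:**
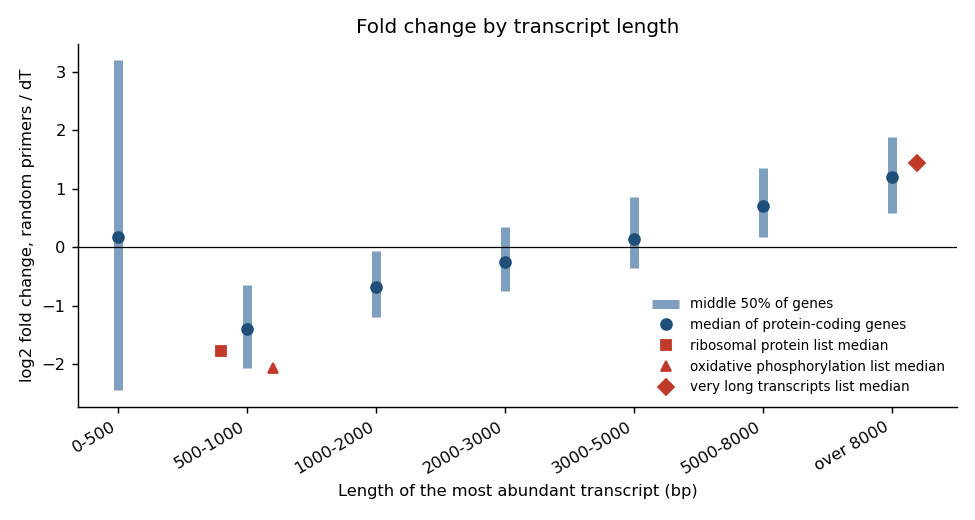
Median log2 fold change of random primers (n = 6 libraries) against dT (n = 3) by the length of each gene's most abundant transcript, in bp. Circles are bin medians of protein-coding genes, bars span the middle 50% of genes, and the other markers are medians of fixed lists (-2.07 for oxidative phosphorylation, 1.44 for very long transcripts).

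Genes of stem cell identity divided within their lists in the same comparison. Of 42 pluripotency genes 5 were higher (Pou5f1, Sall4, Lin28a, Nr6a1 and L1td1) and 12 lower (7 and 14 adjusted over the list alone; median -0.29, adjusted p = 0.000164). Pou5f1, the Oct4 transcription factor gene, stood at 0.78 ± 0.14 (186 ± 17 against 108 ± 21 CPM, adjusted p = 0.000933) but at -0.15 by library totals alone, which also turned Sall4, Lin28a and L1td1 negative. Sox2, its partner factor, was lower (-0.57 ± 0.12, adjusted p = 0.00365), as was the ES cell marker Dppa5a (-2.94 ± 0.09, 123 ± 8.8 against 945 ± 43 CPM), while Nanog was not called (-0.21 ± 0.13, adjusted p = 0.307). The naive pluripotency list (6 higher, 5 lower of 21, or 7 and 7 adjusted over the list alone) held Tfcp2l1 (1.56 ± 0.17) and Klf5 (1.39 ± 0.14) on one side and Zfp42 (-0.98 ± 0.10), Klf2, Klf4, Fbxo15 and Tcl1 on the other. The 5mC dioxygenases Tet1 (2.31 ± 0.10) and Tet2 (1.57 ± 0.17) were higher, and of 34 DNA methylation and chromatin genes 8 were higher and 2 lower, Dnmt3l and Mtf2 (10 and 3 adjusted over the list alone). By library totals alone the median of the naive list went from 0.21 to -0.72 and that of the chromatin list from 0.17 to -0.77. Of 37 cell cycle genes 4 were higher (Cenpf, 1.80 ± 0.28, Cenpe, Mki67 and Top2a, the latter 2 negative by library totals alone) and 12 lower, among them Pcna, the replication clamp (-1.01 ± 0.17), the same as adjusted over the list alone. Glycolysis had 3 higher (Hk1, and Hk2 and Pfkp, which were negative by library totals alone) and 9 lower of 19 (the same adjusted over the list alone), such as Pgam1 (-1.62 ± 0.10).

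Mitochondrial and lineage genes also differed between random primers and dT. Both mitochondrial rRNAs were higher, mt-Rnr1 at 7.64 ± 0.08 and mt-Rnr2 at 1.26 ± 0.03, and of 7 rRNA-annotated loci 5 were higher, with Rn18s-rs5 at 6.84 ± 0.08, Gm42418 at 5.69 ± 0.04 and Gm26917 at 5.42, and 1 lower (Gm15564, -0.32). The 13 mitochondrial mRNAs had 8 higher, such as mt-Co1 (0.94 ± 0.04) and mt-Cytb (0.82 ± 0.06, -0.12 by library totals alone), and 4 lower, mt-Co2 (-6.77 ± 0.74), mt-Atp6 (-4.45 ± 0.38), mt-Nd3 (-4.35) and mt-Co3 (-2.30). Summed with their near-identical copies, a choice made after the data were seen, mt-Co2 turned to 0.28 (adjusted p = 0.00022) and mt-Nd3 to 0.21, and mt-Atp6 (-0.13) and mt-Co3 (-0.12) were not called either. That list had a median of 0.52, a mean of -0.83 and a camera test pointing up, lost with an estimated correlation (adjusted p = 0.116 with an estimated correlation), and its median was -0.41 by library totals alone. Of 15 mitochondrial tRNAs mt-Tf was higher and mt-Ts1 (-7.92 ± 0.42) and mt-Te lower. Of 16 primitive endoderm genes Gata6, Lamc1 (0.71) and the laminin gene Lama1 (1.38 ± 0.20) were higher and Apoe lower (-0.98 ± 0.10, both counts the same adjusted over the list alone), with Lamc1 negative by library totals alone. Zic2 was higher (5.01 ± 1.18) and Tubb3 lower among 6 neuroectoderm genes. Fn1 (0.81, negative by library totals alone) was higher and Vim lower among 8 fibroblast genes. The 6 trophectoderm genes, 3 mesendoderm genes and a pair of 2-cell-like genes gave no call (for mesendoderm 1 higher and 1 lower, and for fibroblast genes 1 and 2, adjusted over the list alone). Actb stood at 0.13 ± 0.09 and Gapdh at -0.24 ± 0.08 (adjusted p = 0.0402). Genes named in these 4 paragraphs as called but outside the naming rule were chosen after their values were seen: Hist1h2ap, Snord47, Gas5, the Snhg genes, Epb41l4aos, Eif4g1, Sall4, Lin28a, Nr6a1, L1td1, Klf2, Klf4, Fbxo15, Tcl1, Dnmt3l, Mtf2, Cenpe, Hk1, Hk2, Pfkp, Gata6, Gm26917, Gm15564, mt-Co3, mt-Nd3 and mt-Tf.

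In all, 2678 of 15682 tested genes were called between random primers and dT (1495 higher, 1183 lower; 4824 without adjustment), and 13 of the 23 fixed lists passed camera, 10 of them with an estimated correlation. Scaling by library totals alone moves the median of all genes from 0.12 to -0.80 and the split to 820 higher and 4328 lower. Without 1 library, calls ended for Tubb3 (any of the 9), Gapdh (N6 replicate 1 or 3, any NSR, dT replicate 2 or 3), and Top2a (any dT). The same happened to Mki67, Vim and Fbxo15 (dT replicate 3), Hk2 and Pfkp (dT replicate 1), Hk1 and Cenpe (dT replicate 2 or 3), and Lin28a (dT replicate 1 or 2). They also ended for Dnmt3l without 5 of the 9 libraries, Snhg5 without 6, and Mtf2, Nr6a1 and Gm15564 without 7.

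NSR lowered rRNA against N6, and few other genes were called (6 libraries with NSR against 6 with N6, each with and without dT). Rn18s-rs5, an 18S rRNA locus, stood at -0.97 ± 0.05 (123000 ± 37000 against 235000 ± 34000 CPM, adjusted p = 5.67e-09) and Gm42418, which lies over an rRNA repeat, at -1.24 ± 0.02. Mir6236 (-1.21 ± 0.05) and AA474408 (-0.92 ± 0.05) were also lower. Of 7 rRNA-annotated loci 3 were lower, the third being mt-Rnr2 (-0.31 ± 0.02, 0.10 by library totals alone), and none higher (5 lower adjusted over the list alone; median -0.33, 0.08 by library totals alone; camera, adjusted p = 1.84e-28). Rn7sk rose with NSR (0.85 ± 0.06, 4270 ± 960 against 2350 ± 450 CPM), as did the signal recognition particle RNAs Rn7s1 and Rn7s2, which share reads (0.71 ± 0.10 each). These were the 3 higher of 20 small RNAs, with none lower (4 and 4 adjusted over the list alone), in a list whose median (-0.06) and mean (-0.40) were below 0 while its test pointed up (adjusted p = 0.0926). Of 63 histones 2 were lower with NSR, or 8 adjusted over the list alone (median -0.49, adjusted p = 5.58e-13). They were Hist1h1c (-0.99 ± 0.16, not called without N6 replicate 2, NSR replicate 3, N6dT replicate 3 or NSRdT replicate 2) and Hist1h2ap (-0.67 ± 0.13, not called without any 1 of the 11 libraries other than NSR replicate 1).

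Of 83 ribosomal protein genes 6 were lower with NSR (2 higher and 16 lower adjusted over the list alone; median -0.03), among them Rps24 (-0.45 ± 0.06) and Rps3 (-0.54 ± 0.08). The call of that list was lost (adjusted p = 0.0063, adjusted p = 0.164 with an estimated correlation), and its median was 0.38 by library totals alone. The call was also lost for 13 mitochondrial mRNAs, none of them called (2 lower adjusted over the list alone; median -0.12, 0.29 by library totals alone, adjusted p = 2.18e-05, adjusted p = 0.0535 with an estimated correlation). Translation factors, none of 30 called, likewise passed camera only with the preset correlation (median 0.10, adjusted p = 0.0365, adjusted p = 0.0827 with an estimated correlation). Pou5f1 (0.06), Nanog (0.14), Sox2 (0.43 ± 0.10, adjusted p = 0.177), Actb (-0.09, positive by library totals alone), Gapdh (0.03), Malat1 (-0.05 ± 0.12), Neat1 (-0.11), Rmrp (0.46 ± 0.11, adjusted p = 0.194), mt-Rnr1 (-0.09) and Tet1 (0.00) were not called. Adjusted over the list alone 1 snoRNA and 1 pluripotency gene were higher. Apart from mt-Rnr2, 1 of 2 mitochondrial rRNAs, the other fixed lists held no called gene. In total 27 genes were called (7 higher, 20 lower; 848 without adjustment), 540 by library totals alone (526 higher, 14 lower, with the median of all genes at 0.42 and not 0.01). The DESeq2 Wald test called 111 (36 higher, 75 lower).

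Adding dT to random primers raised ribosomal protein and oxidative phosphorylation mRNAs (6 libraries with dT against 6 without). Ribosomal protein genes were higher for 67 of 83 and lower for none (74 and 2 adjusted over the list alone; median 0.88, camera, adjusted p = 1.3e-113). The largest rises were in Rps29 (3.75 ± 0.20, 232 ± 19 against 17.3 ± 6 CPM), Rplp2 (3.12 ± 0.12, 324 ± 13 against 37.4 ± 7.1 CPM) and Rps28 (2.83 ± 0.11). Rpl4 was not called (-0.13). Nuclear oxidative phosphorylation genes were higher for 32 of 69 (47 adjusted over the list alone; median 1.00, adjusted p = 9.8e-38), such as Cox8a (2.04 ± 0.18) and Atp5g3 (1.75 ± 0.16). The ES cell marker Dppa5a rose from 123 ± 8.8 to 434 ± 34 CPM (1.82 ± 0.08). So did 4 more of 42 pluripotency genes and none fell: Spp1 (0.45 ± 0.09), Zfp42 (0.40 ± 0.08, adjusted p = 0.0118), Chchd10 and Ifitm1 (6 adjusted over the list alone). Pou5f1 (-0.21), Nanog (0.10), Sox2 (0.19) and Actb (-0.12) were not called. Of the 30 translation factors Eef1b2 (0.78 ± 0.08) and Eif1 (0.88 ± 0.15) were higher (2 and 1 adjusted over the list alone). Of 19 glycolysis genes Pgam1 (0.81 ± 0.09) and Pgk1 (0.51 ± 0.09) were higher and Gapdh lower (-0.32 ± 0.06, adjusted p = 0.0087; 3 and 1 adjusted over the list alone). The long non-coding Gas5 (0.74 ± 0.12) and Epb41l4aos, a snoRNA host, were the 2 higher of 38 (4 adjusted over the list alone).

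rRNA-annotated loci moved down with added dT. All 7 were lower (median -0.39), among them Rn18s-rs5 (-0.56 ± 0.05), mt-Rnr1 (-0.39 ± 0.04) and mt-Rnr2 (-0.39 ± 0.02). Of 20 small RNAs Rn7sk (-0.52 ± 0.06), Rmrp (-0.68 ± 0.11), Rn7s1 and Rn7s2 were lower and none higher (5 adjusted over the list alone). The list call was lost (adjusted p = 6.93e-06, adjusted p = 0.201 with an estimated correlation). Of 63 histones Hist1h1c and Hist1h3b were lower (1 higher and 5 lower adjusted over the list alone; median -0.56, adjusted p = 6.67e-12). Very long transcripts had no call among 76 with a median of -0.19 (0.05 by library totals alone; adjusted p = 8.2e-05). Among 13 mitochondrial mRNAs 4 rose, mt-Co2 (6.74 ± 0.71), mt-Atp6 (4.32 ± 0.35), mt-Nd3 (4.32 ± 0.45) and mt-Co3. The 4 that fell were mt-Co1 and mt-Nd5 (-0.15 and -0.23, both positive by library totals alone), mt-Nd2 (-0.25) and mt-Atp8 (-0.36). The list had a median of -0.09, a mean of 1.24 and a test pointing down (adjusted p = 0.723; 4 and 5 adjusted over the list alone). Summed with their chromosome 1 copies, a choice made after the data were seen, mt-Co2 stood at -0.23 ± 0.03 and mt-Atp6 and mt-Co3 at -0.01 with SEs of 0.03 and 0.02. mt-Nd3 with its copy stood at 0.14 ± 0.05 and was not called. mt-Ts1 (8.03 ± 0.40), a tRNA gene on the strand opposite to the end of mt-Co1, whose reads were not separated from it as the strand of counting is not given, and mt-Te (2.88 ± 0.39) were the 2 higher of 15 mitochondrial tRNAs. Zfp42 was also the 1 naive pluripotency gene higher (1 and 1 adjusted over the list alone), 1 primitive endoderm gene was lower adjusted over the list alone, and the snoRNA, chromatin, cell cycle, 2-cell-like, mesendoderm, neuroectoderm, fibroblast and trophectoderm lists had no call.

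**Figure D4:**
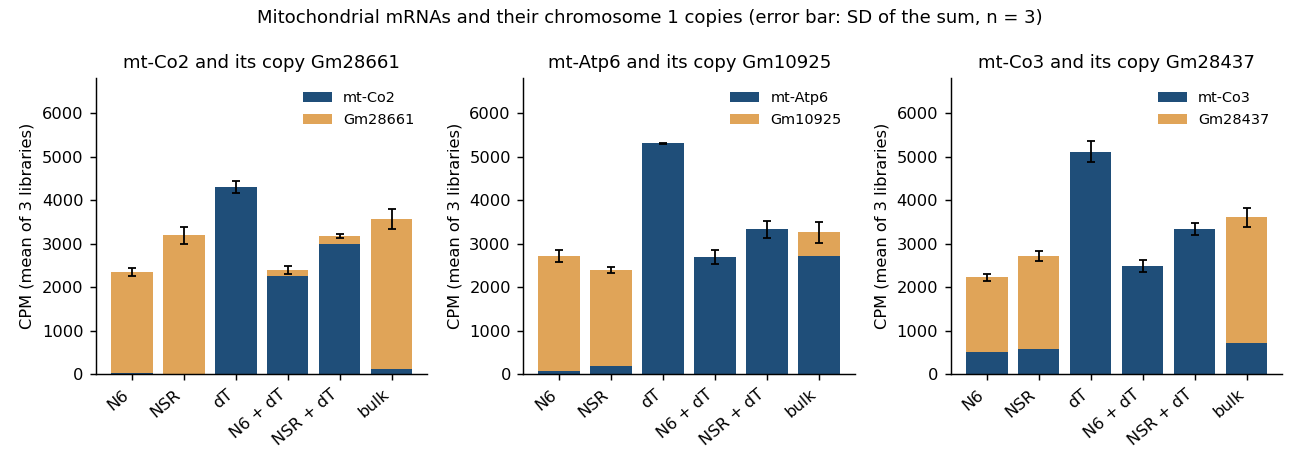
Mean CPM of library totals for mt-Co2, mt-Atp6 and mt-Co3 stacked with their near-identical copies Gm28661, Gm10925 and Gm28437 in the 6 groups. Error bars are the SD of each sum over 3 libraries, and the sums changed with added dT by log2 -0.23, -0.01 and -0.01.

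Added dT gave 341 called genes (282 higher, 59 lower; 1402 without adjustment), 543 by library totals alone (513 higher, 30 lower, with the median of all genes at 0.22 and not -0.02) and 583 by the DESeq2 Wald test (421 higher, 162 lower). Calls ended for Epb41l4aos without any of the 12, Hist1h1c without 11, Rn7s1, Rn7s2 and Ifitm1 without 10, Hist1h3b and Chchd10 without 9, mt-Atp8 without 4 and mt-Co1 without N6dT replicate 1 or NSRdT replicate 1. mt-Co3, mt-Nd2, mt-Nd5, mt-Atp8, Rn7s2, Ifitm1 and Chchd10 stand outside the naming rule and were named after their values were seen.

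Whether added dT acted differently with NSR than with N6 was tested as an interaction, which called 10 genes (7 positive, 3 negative; 688 without adjustment). Gm29216, a nuclear copy of part of mt-Co1, went from 399 ± 92 to 307 ± 40 CPM with N6 and from 4.68 ± 5.4 to 301 ± 27 with NSR (6.38 ± 0.87). Of 83 ribosomal protein genes 3 were positive (18 and 10 adjusted over the list alone; camera, adjusted p = 0.107). They were Rpl14 (1.36 ± 0.23, 61.2 to 202 CPM with N6 and 25.6 to 216 with NSR), Rpl41 (1.03 ± 0.17) and Rps24 (0.80 ± 0.12). Chchd2, a mitochondrial intermembrane protein gene, rose from 31.7 to 83.4 CPM with N6 and from 10.0 to 85.8 with NSR (1.70 ± 0.27), with the pseudogene Rpl27-ps3 (1.82 ± 0.23) and the glycolytic copy gene Eno1b (1.21 ± 0.20) also positive. Gm42418 (-0.33 ± 0.05), Lars2, the mitochondrial leucyl-tRNA synthetase gene whose locus holds an rRNA-like repeat (-0.35 ± 0.06), and Lrrtm2, a synaptic adhesion gene at 15.1 CPM with NSR and 0 with NSRdT, were negative. Of 7 rRNA-annotated loci 1, Gm42418, was negative (4 adjusted over the list alone; median -0.19, adjusted p = 7.45e-09). By the same adjustment both mitochondrial rRNAs and 1 translation factor were negative, and no other list held a call. Every count but 1 fell by more than 1.5 times when a library was left out. It was 3, 4 and 0 genes without N6 replicates 1 to 3, and 2, 7 and 3 without NSR replicates 1 to 3. It was 0, 4 and 0 without N6dT replicates 1 to 3, and 3, 2 and 3 without NSRdT replicates 1 to 3. Library totals alone called 15 (12 positive, 3 negative) and the DESeq2 Wald test 75 (39 positive, 36 negative).

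Against bulk, N6 libraries held more rRNA and less of histone H4, and most ribosomal protein mRNAs were lower (n = 3 against 3 in this and each later comparison). Rn18s-rs5 stood at 6.47 ± 0.05 (308000 ± 3800 against 3470 ± 130 CPM), mt-Rnr1 at 12.96 ± 0.19 and mt-Rnr2 at 10.04 ± 0.13, as 6 of 7 rRNA-annotated loci were higher and none lower. Lars2 (13.36 ± 0.24), Mir6236 (14.58 ± 0.64), AA474408 (8.66 ± 0.12), Ftl1, the ferritin light chain gene (6.04 ± 0.55), and Rps12 (at least 1380-fold, 0 in bulk) were also higher, the last 2 being genes with near-identical copies. Summed with Rps12-ps3, Rps12 was lower than bulk (-0.90, adjusted p = 0.00509). Of 64 histones 33 were lower and 4 higher (43 and 9 adjusted over the list alone; median -1.14, adjusted p = 1.58e-11, adjusted p = 0.0827 with an estimated correlation). H4 mRNAs together stood at 217 ± 20 CPM of library totals against 3492 ± 170, and Hist1h4h at -4.16 ± 0.11. The higher ones were Hist1h2ai, Hist1h2an, Hist1h2bl and Hist1h2br (the last negative by library totals alone). Of 23 small RNAs 10 were lower, such as Rn7sk (-1.41 ± 0.07), Rn7s1 (-2.21 ± 0.08) and Rmrp (-1.73 ± 0.10), and 1 higher, the Ro-bound RNA Rny1 (15 and 2 adjusted over the list alone). Of 52 snoRNAs and scaRNAs 9 were lower, among them Scarna2 (-4.30 ± 0.23; 18 adjusted over the list alone; list adjusted p = 0.0508 with an estimated correlation). Ribosomal protein genes were lower for 59 of 82 and higher for 5 (67 and 7 adjusted over the list alone; median -1.15, adjusted p = 0.0827 with an estimated correlation), with Rpl38 at -2.86 ± 0.10. Oxidative phosphorylation genes were lower for 35 of 69 and higher for 1 (57 and 1 adjusted over the list alone; median -1.17), with Cox7b at -2.06 ± 0.15. Very long transcripts were higher for 13 of 76 (17 adjusted over the list alone; median 0.25), such as the cohesin loader Nipbl (0.93 ± 0.11), but both the median (-1.11) and Nipbl (-0.43) were negative by library totals alone. Of 13 mitochondrial mRNAs 8 were higher, such as mt-Nd4l (3.24 ± 0.13), and 2 lower, mt-Nd3 (-6.11 ± 0.47) and mt-Atp6, which turned to 0.77 and 1.10 when summed with their copies (mt-Atp6 lower by library totals, 2718 ± 130 against 3260 ± 240 CPM). That list (9 and 2 adjusted over the list alone) had a median of 0.88, or -0.48 by library totals alone. Its call and that of the 2 higher mitochondrial rRNAs were lost (adjusted p = 0.0835 with an estimated correlation for each). Dppa5a (-2.18 ± 0.10) and Chchd10 (-1.40) were the 2 of 42 pluripotency genes lower. Nanog (-0.06), Sox2 (-0.04), Gapdh (0.05) and Actb (0.04) were not called, the latter 2 both at -1.32 by library totals alone. Pou5f1 (-0.48, adjusted p = 0.107) and Neat1 (-0.39) were called only without N6 replicate 3.

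Smaller groups in N6 against bulk moved by few members. Lower were the translation factors Eef1b2 (-1.03), Eif1 (-1.27), Eef1d, Eef1g and Eif5a (5 of 30) and the glycolysis genes Pgam1 (-0.78), Tpi1 and Pgk1 (3 of 19, adjusted p = 0.03, adjusted p = 0.305 with an estimated correlation). So were the mitochondrial tRNAs mt-Ty and mt-Ts1 (2 of 14) and 6 of 37 long non-coding RNAs, among them Malat1 (-0.41 ± 0.06, not called without bulk replicate 3). Higher were Rpl10, Rpl11, Rpl35 and Rps27 beside Rps12 in the ribosomal list, Lncenc1, Uqcrc2, Eno1, Tet1 and Mtf2 (2 of 34 chromatin genes), and Top2a, Cenpf, Ccne2 and Mki67 (4 of 37 cell cycle genes). Of these 13 beside Rps12 only Rps27 and Ccne2 stayed positive by library totals alone, and all but Rps27 were not called without bulk replicate 1 nor without replicate 3. The same held for Eef1d, Eef1g, Eif5a, Pgk1, mt-Ty, Rny1 and Hist1h2an, with Rny1 also lost without N6 replicate 1 or 3 and Mtf2 without N6 replicate 3, while mt-Ts1 was not called without bulk replicate 1 or 2. Adjusted over the list alone the counts higher and lower were 3 and 7 for translation factors, 1 and 6 for glycolysis, 1 and 2 for mitochondrial tRNAs and 2 and 7 for long non-coding RNAs. They were unchanged for the chromatin, cell cycle, pluripotency and rRNA lists. Naive pluripotency (21), primitive endoderm (16), mesendoderm (3), neuroectoderm (6), fibroblast (7) and trophectoderm (6) genes had no call. The primitive endoderm median of -2.28 stands beside bulk replicate 2, which held these genes at a median of 4.11 above the other bulk libraries. The genes named here that the naming rule did not reach (mt-Atp6, Rny1, Lncenc1, Uqcrc2, Eno1, Ccne2, Pgk1, Rpl10, Rpl11, Rpl35, Rps27, Eef1d, Eef1g, Eif5a and the 4 higher histones) were chosen after their values were seen. In all 1096 of 15207 genes were called (503 higher, 593 lower), 8712 by library totals alone (142 higher, 8570 lower, median of all genes -1.39), and 10 of 22 lists passed camera. Without N6 replicates 1 to 3 in turn 2088, 2025 and 2151 were called, and without bulk replicates 1 to 3 364, 402 and 359.

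**Figure D5:**
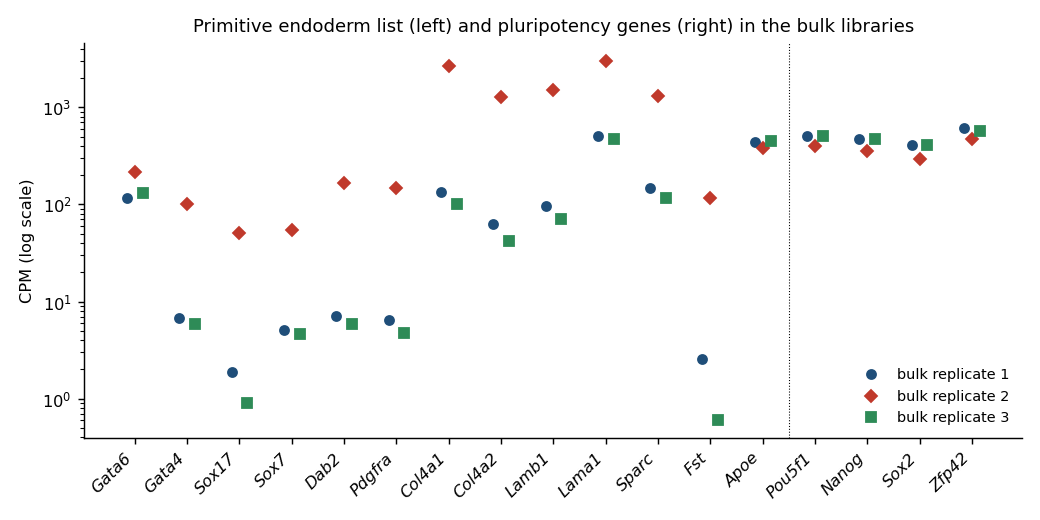
CPM of library totals, on a log scale, in the 3 bulk replicates for primitive endoderm genes (left of the dotted line) and pluripotency genes (right). Each point is 1 library, and Col4a1 stood at 2640 CPM in replicate 2 and 117 on average in the other 2.

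NSR libraries held more rRNA than bulk, and most histone and ribosomal protein mRNAs were lower. The rRNA loci were higher for 6 of 7 (Rn18s-rs5 5.70 ± 0.08, Gm42418 4.06 ± 0.05), with mt-Rnr1 at 12.96 ± 0.19, Lars2 at 13.04 ± 0.24, and Mir6236 at 13.55 ± 0.65. Rps12 was at least 1980-fold higher and Tnf, an inflammatory cytokine gene, at least 578-fold higher, but Rps12 summed with Rps12-ps3 was lower (-0.45, adjusted p = 0.0207). Of 64 histones 40 were lower and 3 higher, Hist1h2an, Hist1h2bl and Hist1h3h (46 and 4 adjusted over the list alone; median -1.72, adjusted p = 0.0663 with an estimated correlation), with Hist1h4f at -5.58 ± 0.37 and Hist1h4c at -4.42 ± 0.17. Small RNAs were lower for 12 of 23, such as Rpph1 (-3.07 ± 0.17) and Rmrp (-1.16 ± 0.14), and higher for Rnu11 (16 and 1 adjusted over the list alone; adjusted p = 0.0644 with an estimated correlation). Of 54 snoRNAs and scaRNAs 13 were lower, such as Scarna2 (19 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). Of 82 ribosomal protein genes 59 were lower (67 adjusted over the list alone; median -1.28, adjusted p = 0.0835 with an estimated correlation), with Rpl14 at -4.23 ± 0.12 and Rps29 at -4.37 ± 0.31. The 5 higher ones were Rps12, Rps27, Rps13, Rpl35 and Rpl10. Oxidative phosphorylation genes were lower for 38 of 69 (51 adjusted over the list alone; median -1.30), with Cox8a at -2.76 ± 0.19. Very long transcripts were higher for 9 of 76 (12 adjusted over the list alone; median 0.35, -0.65 by library totals alone), among them Dst (0.85 ± 0.08, -0.16 by library totals alone). Mki67, a marker of dividing cells, was also higher (0.82 ± 0.09, -0.19 by library totals alone). Fut9, which makes the SSEA-1 antigen of mouse ES cells (1.48 ± 0.16), and Ifitm1 were higher and Dppa5a (-2.13 ± 0.09), Chchd10, Lefty1 and Lin28a lower among 42 pluripotency genes. Of 13 mitochondrial mRNAs 8 were higher (mt-Nd2 1.66) and 2 lower, mt-Nd3 (-6.95 ± 0.37) and mt-Atp6 (median 0.71, -0.29 by library totals alone). Summed with their copies these 2 turned to 1.11 and 0.56 (mt-Atp6 lower by library totals, 2396 ± 72 against 3260 ± 240 CPM). The list call was lost (adjusted p = 0.164 with an estimated correlation), as for the 2 higher mitochondrial rRNAs (adjusted p = 0.106 with an estimated correlation). Pou5f1 (-0.39), Nanog (0.00, negative by library totals alone), Sox2 (0.61, adjusted p = 0.0916), Gapdh (0.02, negative by library totals alone), Actb (-0.10) and Neat1 were not called.

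Among smaller groups of NSR against bulk, Eif3a, Eif3c and Eif5b were higher and Eef1b2, Eif1, Eef1d, Eef1g and Eif5a lower of 30 translation factors. Tet1, Suz12, Smc3 and Hells were higher of 34 chromatin genes (adjusted p = 0.00853, adjusted p = 0.205 with an estimated correlation). Top2a and Cenpf, with Mki67, were higher and Ccnd2, Gmnn and Cdk2 lower of 37 cell cycle genes. Pgam1, Tpi1, Aldoa and Pgk1 were lower of 19 glycolysis genes (adjusted p = 0.0133, adjusted p = 0.201 with an estimated correlation). Of 37 long non-coding RNAs 6 were lower, such as Gas5 (-0.88 ± 0.12), and Dleu2 higher. Of 13 mitochondrial tRNAs mt-Tf, mt-Tl1 and mt-Tp were higher and mt-Ty and mt-Ts1 lower, and of 7 fibroblast genes Pdgfrb was lower. Eif3a, Eif3c, Eif5b, Tet1, Suz12, Smc3, Hells, Top2a, Cenpf, Rpl10, Ifitm1 and Dleu2 were negative by library totals alone. Calls ended without bulk replicate 1 and without bulk replicate 3 for each called gene in this paragraph and the one before given without an error, save Eef1b2, Eif1, Pgam1, Tpi1, Chchd10, Rps12, Rps13, Rps27, Rpl35, Hist1h2bl, Hist1h3h, Tnf, mt-Nd2 and mt-Ts1. They also ended without NSR replicate 1 for Eef1d, Dleu2 and Ccnd2, without NSR replicate 2 for mt-Atp6 and Ccnd2, and without NSR replicate 3 for Dleu2 and Ccnd2. Outside the naming rule, so chosen after their values were seen, were the translation factors other than Eef1b2 and Eif1, Smc3, Hells, Ccnd2, Gmnn, Cdk2, Tpi1, Pgk1, Dleu2, mt-Tf, mt-Tl1, mt-Atp6, Rnu11, Ifitm1, Chchd10, Lefty1, Lin28a, Rps27, Rps13, Rpl35, Rpl10 and the 3 higher histones. Adjusted over the list alone the counts higher and lower were 5 and 6 for translation factors, 3 and 5 for pluripotency, 4 and 4 for cell cycle and 0 and 5 for glycolysis. They were 2 and 9 for long non-coding RNAs, 9 and 2 for mitochondrial mRNAs, 0 and 1 for mesendoderm and 1 and 2 for trophectoderm, and unchanged for the lists not given here. The naive list (21) and the lists of primitive endoderm (17, median -2.93 beside the high bulk replicate 2), mesendoderm (3), neuroectoderm (6) and trophectoderm (6) had no call. In all 1336 of 15418 genes were called (619 higher, 717 lower), 6102 by library totals alone (180 higher, 5922 lower, median of all genes -1.03), and 11 of 22 lists passed camera. Without NSR replicates 1 to 3 in turn 2537, 2504 and 2581 were called, and without bulk replicates 1 to 3 384, 443 and 365.

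dT libraries held less histone mRNA and Malat1 than bulk, and most measured small RNAs were lower. Of 61 histones 53 were lower and none higher (58 and 1 adjusted over the list alone; median -6.86, or -6.30 with 13 genes at their bound; adjusted p = 0.0163 with an estimated correlation too). Hist1h4c was lower by at least 945-fold and Hist1h3b by at least 694-fold, while Hist1h2ap did not differ by test (0.02 ± 0.09, 290 against 286 CPM). Rpph1 stood at -14.18 ± 0.66, Rmrp at -7.39 ± 0.17, Rn7sk at -5.05 ± 0.08 and Malat1 at -7.33 ± 0.36 (55.2 ± 20 against 8870 ± 180 CPM). Of 24 small RNAs 17 were lower and 1, Rnu1a1, higher (17 and 2 adjusted over the list alone; median -6.09, -4.32 with bounds, adjusted p = 0.0829 with an estimated correlation). Of 56 snoRNAs and scaRNAs 20 were lower (24 adjusted over the list alone), Scarna10 by at least 576-fold. Of 39 long non-coding RNAs 13 were lower, such as Neat1 (-2.55 ± 0.20) and the imprinted Kcnq1ot1 (-2.53 ± 0.17). Ribosomal protein genes were higher for 60 of 83 and lower for 6 (64 and 7 adjusted over the list alone; median 0.72), with Rpl35 at 2.40 ± 0.09 and Rpl4 at 0.88 ± 0.07. Oxidative phosphorylation genes were higher for 33 of 69 (40 and 1 lower adjusted over the list alone; median 0.64), such as Ndufb6 (1.55 ± 0.14). Translation factors were higher for 11 of 30 and lower for Eif4g1 (-1.27 ± 0.08) and Eif4b. Very long transcripts were lower for 33 of 76 (50 adjusted over the list alone; median -1.16), such as Ahnak (-2.88 ± 0.21). Of 7 rRNA-annotated loci mt-Rnr1, mt-Rnr2 (8.68 ± 0.14), Gm23935 and Gm15564 were higher and Gm26917 (-5.49 ± 0.08), Gm42418 (-1.07) and Rn18s-rs5 (-0.74) lower (camera, adjusted p = 0.346). Of 13 mitochondrial mRNAs 9 were higher, such as mt-Co2 (5.42 ± 0.10), and mt-Nd1, mt-Nd3 and mt-Cytb lower (median 1.15, adjusted p = 0.284 with an estimated correlation). Summed with their copies mt-Co2 stood at only 0.53 (4307 ± 130 against 3568 ± 230 CPM of library totals) and mt-Nd3 turned to 0.74. The call of the 2 higher mitochondrial rRNAs was lost too (adjusted p = 0.171 with an estimated correlation).

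Stem cell genes in dT against bulk went both ways. Dppa5a (0.80 ± 0.07), Ifitm1 (1.93 ± 0.14), Spp1 (1.51 ± 0.12) and Sox2 (0.87 ± 0.15, adjusted p = 0.0104) were among 10 of 42 pluripotency genes higher. Pou5f1 (-1.21 ± 0.18, adjusted p = 0.00968) was among 6 lower (14 and 7 adjusted over the list alone; adjusted p = 0.000744, adjusted p = 0.494 with an estimated correlation). Tfcp2l1 (-1.65 ± 0.14), Tet2, Klf5 and Tbx3 were the 4 naive pluripotency genes lower, with 7 of 21 higher. Tet1 (-1.68 ± 0.11) was among 6 of 34 chromatin genes lower, with Suz12, Rad21 and Mtf2 higher. Cell cycle genes were higher for 11 of 37 and lower for Cenpe (adjusted p = 1.01e-05, adjusted p = 0.0874 with an estimated correlation). In glycolysis Pgam1 (0.80), Eno1 (0.87), Ldhb and Aldoa were higher and Hk2, Slc2a3 and Pfkp lower (19 genes, adjusted p = 0.0376, adjusted p = 0.19 with an estimated correlation). Apoe (0.94) was higher and Pdgfra and Sox7 lower among 16 primitive endoderm genes (median -2.72, beside the high bulk replicate 2). Mesp2 and Tbx6 were lower among 4 mesendoderm genes and Tubb3 higher among 6 neuroectoderm genes. Vim was higher and Pdgfrb lower among 9 fibroblast genes, mt-Ts1 higher and mt-Ty lower among 12 mitochondrial tRNAs, and none of 6 trophectoderm genes was called. Adjusted over the list alone the counts higher and lower were 8 and 6 for naive pluripotency, 4 and 8 for chromatin, 12 and 1 for cell cycle, 7 and 4 for glycolysis and 1 and 6 for primitive endoderm. They were 1 and 2 for mesendoderm and for fibroblast genes, 1 and 1 for neuroectoderm and 15 and 2 for translation factors. For mitochondrial mRNAs they were 9 and 4 and for mitochondrial tRNAs 2 and 2, and unchanged for rRNA loci and long non-coding RNAs. Gapdh (0.29, adjusted p = 0.0721, called without dT replicate 1), Nanog (0.19) and Actb (-0.16) were not called. In all 2957 of 15708 genes were called (1084 higher, 1873 lower), 2813 by library totals alone (617 higher, 2196 lower, with the median of all genes at -0.45 and not -0.19), and 12 of 22 lists passed camera. Without dT replicates 1 to 3 in turn 5030, 5089 and 4928 were called, and without bulk replicates 1 to 3 357, 1347 and 299. More were higher than lower without bulk replicate 1 (223, 134) or 3 (180, 119) and with the replicate block (364, 342). Without bulk replicate 1 or 3 calls ended for Pou5f1, Sox2, Tet2, Klf5, Tbx3, Suz12, Rad21, Mtf2, Cenpe, Aldoa, Ldhb, Slc2a3 and Pfkp. The same held for Sox7, Mesp2, Tbx6, Tubb3, Vim, Pdgfrb, mt-Ty, mt-Nd1, mt-Cytb, Rnu1a1 and Eif4b. Calls ended for Hk2 without replicate 3, and for Pdgfra without any of the 6, with Sox7 and Cenpe also lost without dT replicate 2. Gm23935, Gm15564, Gm42418, Rn18s-rs5, mt-Nd1, mt-Nd3, mt-Cytb, Rnu1a1, Eif4b, Klf5, Tbx3, Suz12, Rad21, Mtf2, Cenpe, Ldhb, Aldoa, Hk2, Slc2a3, Pfkp and Pdgfra were named after their values were seen.

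N6dT libraries held less histone mRNA than bulk, while ribosomal protein mRNAs went both ways. Of 82 ribosomal protein genes 15 were higher and 29 lower (21 and 39 adjusted over the list alone). The list had a median of -0.20, a mean of 0.03 and a test pointing down (adjusted p = 0.00502, adjusted p = 0.776 with an estimated correlation). Rps27 stood at 4.25 ± 0.13 and Rpl28 at -1.51 ± 0.09. Of 69 oxidative phosphorylation genes Uqcrc2 was higher and Cox7c (-1.14 ± 0.13), Cox4i1 and Atp5l lower (2 and 11 adjusted over the list alone; median -0.31, adjusted p = 0.164 with an estimated correlation). Of 63 histones 41 were lower, such as Hist1h4j (-6.96 ± 0.39) and Hist1h3a (-5.46 ± 0.31), and Hist1h2bl, Hist1h2bn and Hist1h2br higher (45 and 3 adjusted over the list alone; median -1.55). Small RNAs were lower for 10 of 22, such as Rn7sk (-1.88 ± 0.07) and Rmrp (-2.27 ± 0.09). Adjusted over the list alone 16 were lower and 2 higher (adjusted p = 0.0949 with an estimated correlation). Of 51 snoRNAs and scaRNAs 13 were lower, such as Scarna2 (-5.15 ± 0.31; 22 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). Malat1 (-0.50 ± 0.05) and Snhg3 were the 2 of 37 long non-coding RNAs lower. rRNA loci were higher for 6 of 7 (Rn18s-rs5 6.13 ± 0.08) and lower for Gm26917 (adjusted p = 0.0827 with an estimated correlation). The pair of mitochondrial rRNAs was higher (adjusted p = 0.205 with an estimated correlation). Of 13 mitochondrial mRNAs 11 were higher, such as mt-Co2 (5.43 ± 0.10), and mt-Nd3 lower (median 1.18, -0.01 by library totals alone). With their copies added mt-Co2 stood at only 0.62 (adjusted p = 0.00224), was below bulk by library totals (2398 ± 97 against 3568 ± 230 CPM), and mt-Nd3 turned to 1.08. mt-Ts1, mt-Te and mt-Tp were higher and mt-Ty lower among 11 mitochondrial tRNAs (adjusted p = 0.0457, adjusted p = 0.258 with an estimated correlation). Pou5f1 was lower (-0.65 ± 0.12, adjusted p = 0.0307), Chchd10 lower and Ifitm1 higher among 42 pluripotency genes, and Nanog and Sox2 were not called.

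The other groups of N6dT against bulk held few calls. Cenpf, Smg1, Usp9x, Kmt2c and Chd8 were the 5 of 76 very long transcripts higher (10 adjusted over the list alone; median 0.15, -1.05 by library totals alone, adjusted p = 0.102 with an estimated correlation). Suz12 was higher among 34 chromatin genes, Cenpf and Ccna2 among 37 cell cycle genes, and Eif1, Eef1g and Eif5a lower among 30 translation factors. Glycolysis had no call among 19 genes (adjusted p = 0.00772, adjusted p = 0.205 with an estimated correlation). Nor had naive pluripotency (21), primitive endoderm (15, median -2.38 beside the high bulk replicate 2), mesendoderm (3), neuroectoderm (6), fibroblast (7) or trophectoderm genes (6). All of Cenpf, Smg1, Usp9x, Kmt2c, Chd8, Suz12, Ccna2, Uqcrc2, Ifitm1, Hist1h2bn and Hist1h2br were negative by library totals alone. These genes, with Eif1, Eef1g, Eif5a, Cox4i1, Atp5l, Snhg3, Chchd10, Pou5f1, mt-Te, mt-Tp and mt-Ty, were not called without bulk replicate 1 or without replicate 3. Calls ended also without N6dT replicate 3 for Usp9x, Pou5f1, Suz12 and Chchd10, without replicate 1 for Usp9x and Suz12 and without replicate 2 for Usp9x. Adjusted over the list alone the counts higher and lower were 12 and 1 for mitochondrial mRNAs, 4 and 2 for mitochondrial tRNAs, and 2 and 4 for pluripotency. They were 6 and 0 for chromatin and 1 and 6 for glycolysis, and unchanged for the other lists without such a count above. Gm26917, mt-Nd3, mt-Tp, Hist1h2bl, Hist1h2bn, Hist1h2br, Cox4i1, Atp5l, Eif1, Smg1, Chd8 and Chchd10 were named after their values were seen. In all 730 of 15234 genes were called (411 higher, 319 lower), 8087 by library totals alone (129 higher, 7958 lower, median of all genes -1.23), and 11 of 22 lists passed camera. Without N6dT replicates 1 to 3 in turn 1468, 1377 and 1367 were called, and without bulk replicates 1 to 3 221, 253 and 207.

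NSRdT libraries held less histone mRNA than bulk. Of 63 histones 44 were lower, such as Hist1h4f (-5.42 ± 0.15) and Hist1h4j (-7.18 ± 0.44), and Hist1h2bl was higher (54 and 2 adjusted over the list alone; median -2.38). Of 26 small RNAs 13 were lower, such as Rn7sk (-1.08 ± 0.05), Rmrp (-1.96 ± 0.08), Rpph1 (-4.01 ± 0.14) and the U3 RNA gene Rnu3a (at least 122-fold). The U3 copies Rnu3b1 to Rnu3b4, which share reads with it, were higher at 6.92 each (15 and 4 adjusted over the list alone; adjusted p = 0.0593 with an estimated correlation). snoRNAs and scaRNAs were lower for 10 of 53, such as Scarna2 (-5.16 ± 0.22; 17 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation). Of 82 ribosomal protein genes 12 were higher and 32 lower (21 and 40 adjusted over the list alone; median -0.24, adjusted p = 0.64 with an estimated correlation), with Rps27 at 4.25 ± 0.13. Of 69 oxidative phosphorylation genes Cox7c (-1.26 ± 0.15), Cox4i1, Atp5b, Atp5h and Uqcr11 were lower (16 and 1 higher adjusted over the list alone; adjusted p = 0.0883 with an estimated correlation). Malat1 (-0.62 ± 0.04) and Neat1 (-0.59 ± 0.11) were lower and Tug1, Lncenc1 and Snhg14 higher among 37 long non-coding RNAs. rRNA loci were higher for 6 of 7 (Rn18s-rs5 4.94 ± 0.06) and lower for Gm26917 (adjusted p = 0.201 with an estimated correlation). Both mitochondrial rRNAs were higher (list adjusted p = 0.715). Of 13 mitochondrial mRNAs 11 were higher, such as mt-Co2 (5.36 ± 0.10), and mt-Nd3 lower (median 1.00, adjusted p = 0.0523 with an estimated correlation). Sums with the copies put mt-Co2 at only 0.55 (adjusted p = 0.00405), below bulk by library totals (3175 ± 41 against 3568 ± 230 CPM), and turned mt-Nd3 to 1.10. Among 42 pluripotency genes, those lower included Pou5f1 (-0.63 ± 0.12, adjusted p = 0.0325), Lin28a, Mybl2 and Chchd10, those higher included Ifitm1, and Nanog and Sox2 were not called.

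Few members moved in the other groups of NSRdT against bulk. Ranbp2, Cenpf, Usp9x and Brca2 were higher and the chromatin remodeller Chd6 lower (-1.23 ± 0.14) among 76 very long transcripts (7 and 2 adjusted over the list alone; median 0.15, -0.57 by library totals alone, adjusted p = 0.0827 with an estimated correlation). Eif1a was higher and Eif1, Eef1g and Eif5a lower among 30 translation factors. Ezh2 was higher among 34 chromatin genes, Cenpf higher and Tyms lower among 37 cell cycle genes. Aldoa and Tpi1 were lower among 19 glycolysis genes (adjusted p = 0.00566, adjusted p = 0.211 with an estimated correlation). mt-Ts1 and mt-Te were higher and mt-Ty lower among 12 mitochondrial tRNAs. Naive pluripotency (21), primitive endoderm (17, median -2.34 beside the high bulk replicate 2), mesendoderm (3), neuroectoderm (6), fibroblast (8) and trophectoderm genes (6) had no call. Usp9x, Brca2, Eif1a, Ezh2, Tug1, Lncenc1 and Snhg14 were negative by library totals alone. Without bulk replicate 1 or without replicate 3 calls ended for these 7 and for Cenpf, Eif1, Eif5a, Tyms, Aldoa, Tpi1, Neat1, Pou5f1, Lin28a, Mybl2, Chchd10, Ifitm1, Cox7c, Cox4i1, Atp5b, Atp5h, Uqcr11, Rnu3b1 to Rnu3b4, mt-Te and mt-Ty, and for Ranbp2 without replicate 3. They ended also without NSRdT replicate 1 for Tpi1, Eif1a, Lncenc1, Pou5f1, Neat1 and Chchd10, without replicate 2 for Tpi1, Eif1a, Lncenc1 and Mybl2, and without replicate 3 for Pou5f1, Neat1 and Mybl2. The counts adjusted over the list alone were 12 and 1 for mitochondrial mRNAs, 3 and 3 for mitochondrial tRNAs and 4 and 3 for long non-coding RNAs. They were 5 and 7 for translation factors, 5 and 5 for pluripotency, 6 and 1 for chromatin, 2 and 1 for cell cycle and 1 and 5 for glycolysis, and unchanged for rRNA loci. Gm26917, mt-Nd3, Hist1h2bl, the Rnu3b copies, Lncenc1, Snhg14, Uqcr11, Cox4i1, Atp5h, Eif1a, Eif5a, Brca2, Mybl2 and Chchd10 were named after their values were seen. In all 821 of 15553 genes were called (419 higher, 402 lower), 3921 by library totals alone (179 higher, 3742 lower, median of all genes -0.75), and 9 of 22 lists passed camera. Without NSRdT replicates 1 to 3 in turn 1626, 1770 and 1640 were called, and without bulk replicates 1 to 3 231, 292 and 225.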

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

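The interaction test and the splits were fixed before the data were examined, and the tests of mt-Co2, mt-Atp6 and mt-Co3 were chosen after their values were seen. Over 100 splits of the 12 libraries, 3, the real one with its 10 included, gave at least 10 interaction calls, and the highest other split gave 267, which points to a structure of the samples: it sets all 6 libraries with dT added against the 6 without. The called interaction values are 1.70 for Chchd2, 1.21 for Eno1b, 6.38 for Gm29216, -0.33 for Gm42418, -0.35 for Lars2, -10.31 for Lrrtm2 (fitted against 0 counts in NSRdT, so no measure of size), 1.36 for Rpl14, 1.82 for Rpl27-ps3, 1.03 for Rpl41 and 0.80 for Rps24. ERCC spike-in entries took 0.422% of counts in RT-RamDA (SD 0.064, n = 15, range 0.355 to 0.536) and 1.01% in bulk (SD 0.19, n = 3), with 23 of 92 sequences seen in every library, and these were not used to scale counts.

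The rise of mt-Co2, mt-Atp6 and mt-Co3 with added dT can be read as reads moving between a mitochondrial gene and its nuclear copy. mt-Co2 shares 651 of its 654 31-mers with Gm28661 on chromosome 1, and with N6 mt-Co2 stood at 29.8 and the copy at 2328 CPM while with N6dT they stood at 2258 and 140. If reads only change name, the sum of gene and copy should stay put, and the sums moved by at most -0.23 in log2 (SE 0.03), which fits reads shared with the copies. If oligo(dT) primed all mitochondrial mRNAs better, the 8 mitochondrial mRNAs sharing under 90% of their 31-mers should rise as well, and their median was -0.15, which argues against that. Gm29216, which shares 449 of 1515 31-mers of mt-Co1, is in the same stretch of chromosome 1, and no biological explanation was tested, because the design gives no group for one.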

How the results depend on the processing

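Over all settings the 593 named gene results were the same in 8326 runs, lost a call in 1206 (752 with 1 library left out), gained one in 35 and turned in 97, all but 18 of these under library totals alone. Library totals alone called 5148 for random primers against dT, 540 for NSR against N6, 543 for added dT, 8712 for N6, 6102 for NSR, 8087 for N6dT and 3921 for NSRdT against bulk. The DESeq2 Wald test called 111 for NSR against N6, 583 for added dT, 75 for the interaction, and 2075, 2324, 1766 and 1858 for N6, NSR, N6dT and NSRdT against bulk. With no filter on low counts NSR against N6 gave 89, the interaction 53, and these 4 bulk comparisons 607, 668, 367 and 380. A replicate block gave 5 for the interaction and 572, 584, 706, 312 and 303 for N6, NSR, dT, N6dT and NSRdT against bulk. A fit of all 18 libraries gave 584, 701, 322 and 361 for N6, NSR, N6dT and NSRdT against bulk. NSR against N6 gave 44 within libraries without dT and 10 within those with dT, added dT 178 within N6 and 193 within NSR, and the interaction 4 when fitted on the compared libraries only. With 1 library left out counts ranged from 0 to 7 for the interaction and, against bulk, from 359 to 2151 for N6, 365 to 2581 for NSR, 299 to 5089 for dT, 207 to 1468 for N6dT and 225 to 1770 for NSRdT, the low ends all without bulk replicate 3.

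With an estimated correlation camera passed 3 lists for NSR against N6 and 4, 3, 6, 2 and 1 for N6, NSR, dT, N6dT and NSRdT against bulk, and fry passed 11 for added dT. For library measures, detected genes differed by 394 between NSR and N6 and by 410 for added dT without thinning (neither called), and by 121 between NSR and N6 after removing rRNA-annotated and mitochondrial genes (not called). The rRNA-annotated share of RT-RamDA against bulk was 16.5 points with nuclear loci only, and 26.2 to 29.5 with 1 library left out. With mitochondrial mRNAs only the mitochondrial share turned to 1.62 points for dT against random primers and 0.889 for added dT, and was 0.0360 for RT-RamDA against bulk. With 5 near-identical copies counted in, chosen after seeing the data, these were 0.927, 0.203 and -0.367. NSR against N6 was called for the histone share of the counts left after removing rRNA-annotated and mitochondrial genes (-0.109), for the correlation over genes at 10 CPM or more (-0.00746) and for Pearson correlation (-0.00478). With 1 library left out the histone share difference of NSR from N6 ranged from -0.0111 to -0.00497 and that of the correlation from -0.00409 to -0.00169. Median CV over genes at 100 CPM or more was 0.159 with N6, 0.163 with NSR, 0.190 with dT, 0.146 with N6dT, 0.146 with NSRdT and 0.0557 in bulk, and 0.305 with N6dT when thinned. With 1 library left out CVs were 0.249 to 0.257 with N6, 0.253 to 0.265 with NSR, 0.312 to 0.322 with dT, 0.239 to 0.242 with N6dT, 0.237 to 0.239 with NSRdT and 0.0435 to 0.0748 in bulk.

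Log2 fold changes that turned under library totals alone were, for random primers against dT, mt-Nd4 -0.41, mt-Cytb -0.12, Lncenc1 -0.21, Kdm5b -0.28, Top2a -0.56, Mki67 -0.06, Lamc1 -0.22, Fn1 -0.12, Pou5f1 -0.15, Actb -0.80, Hk2 -0.33, Pfkp -0.34, Sall4 -0.15, Lin28a -0.34 and L1td1 -0.36. For NSR against N6 they were mt-Rnr2 0.10 and Actb 0.32, and for added dT mt-Co1 0.09 and mt-Nd5 0.01. For N6 against bulk they were mt-Co1 -0.67, mt-Nd4 -0.28, Huwe1 -0.91, Nipbl -0.43, Ankhd1 -0.48, Tet1 -0.72, Mtf2 -0.75, Top2a -0.90, Mki67 -0.67, Cenpf -0.24, Gapdh -1.32, Actb -1.32, Rpl10 -0.81, Uqcrc2 -0.77, Rpl11 -0.67, Rpl35 -0.68, Eno1 -0.88, Hist1h2br -0.34 and Lncenc1 -0.71. For NSR against bulk they were mt-Co1 -0.33, mt-Cytb -0.56, Usp9x -0.31, Dst -0.16, Mki67 -0.19, Tet1 -0.39, Suz12 -0.26, Top2a -0.47, Cenpf -0.17, Gapdh -0.98, Nanog -1.0, Rpl10 -0.54, Smc3 -0.44, Eif3a -0.51, Hells -0.38, Ifitm1 -0.26, Eif5b -0.11, Eif3c -0.44 and Dleu2 -0.28. For N6dT against bulk they were mt-Co1 -0.65, mt-Atp6 -0.01, Uqcrc2 -0.38, Usp9x -0.79, Cenpf -0.60, Kmt2c -0.47, Ifitm1 -0.20, Suz12 -0.60, Ccna2 -0.67, Sox2 -0.80, Smg1 -0.76, Chd8 -0.72, Hist1h2br -0.44 and Hist1h2bn -0.60. For NSRdT against bulk they were mt-Co1 -0.17, Tug1 -0.22, Usp9x -0.09, Ezh2 -0.21, Brca2 -0.08, Eif1a -0.18, Lncenc1 -0.17 and Snhg14 -0.16. Summed with their chromosome 1 copies, mitochondrial genes turned for random primers against dT (mt-Co2 0.28) and for added dT (mt-Co2 -0.23, mt-Atp6 -0.01 and mt-Co3 -0.01), a setting chosen after seeing the data. With mt-Nd3 and Rps12 summed with theirs as well, also chosen after, these values stayed, and mt-Nd3 turned to 0.21 for random primers against dT. Against bulk mt-Nd3 turned to 0.77 for N6, 1.11 for NSR, 0.74 for dT, 1.08 for N6dT and 1.10 for NSRdT, mt-Atp6 to 1.10 for N6 and 0.56 for NSR, and Rps12 to -0.90 for N6 and -0.45 for NSR.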

Other observations

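Outside the fixed lists 2 transcripts marked NSR primers. Tnf had 240 to 741 counts in each of the 6 libraries with NSR primers and 0 in the other 12 (86.1 ± 5.5 CPM with NSR, 49.7 ± 12 with NSRdT, SD, n = 3 each; edgeR quasi-likelihood F test, NSR against N6, BH adjusted p = 1.55e-06). Igkv1-110, an immunoglobulin kappa variable gene, had 61 to 115 counts in the same 6 and 0 in the other 12 (adjusted p = 0.00386). These 2 were the genes with at least 20 counts in each NSR library and at most 3 elsewhere, no gene met the same rule for N6, and the rule was set after the values were seen. It was not tested whether NSR oligonucleotides or a mispriming product map to these 2 genes.

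The tests of length and of pseudogene copies for the ribosomal protein pattern were fixed before their values were seen, and the test of length as the whole cause and all tests of bulk replicate 2 were chosen after. Ribosomal protein mRNAs are short (median 733 bp), and mRNAs of 500 to 1000 bp had a median of -1.40 for random primers against dT (0.17 under 500 bp), so length could give the pattern. Less the median of genes of like length, the ribosomal list stood at -0.62 (interval over genes -0.91 to -0.49), which crosses the bound set at -0.5 and leaves length open as a large part. Of its 83 genes 80 lie below genes of like length. The chance range, 33 to 50, takes genes as independent, so length as the whole cause stays open. Sums of each gene with every gene sharing 20% or more of its 31-mers had a median of -1.74 (interval -1.99 to -1.61), which argues against reads lost to pseudogenes. The design gives no group for a biological explanation, and none was tested.

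Bulk replicate 2 held primitive endoderm genes far above the other bulk libraries. Col4a1 (chromosome 8, 11198423 to 11312826), a collagen gene, stood at 2640 against 117 CPM, Sox17 36.8-fold, Dab2 25.7-fold, Gata4 16.2-fold and Gata6 1.75-fold higher, while Pou5f1 stood at 0.79-fold and Nanog at 0.758-fold. That 22 of 24 genes exceed both other libraries by more than 1.5-fold, and 22 of 24 their counting interval, prompted the question, so neither tests counting noise or RNA of primitive-endoderm-like cells as a source. The median log2 ratio was 4.11, against -0.30 to 0.21 for the other lineage lists. A share of differentiated cells and a mix-up with a Gata6-induced sample both stay open and cannot be told apart.

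The splits of the libraries were fixed before the data were examined. For random primers against dT 1 of 84 splits reached 2678 calls, the real one, with 565 the highest other, for NSR against N6 1 of 100 (27 calls, highest other 10), and for added dT 1 of 100 (341 calls, highest other 17), which argues against chance groups. For each bulk comparison 1 of 10 splits reached the real count (1096, 1336, 2957, 730 and 821, highest other 0 in each), and 10 splits are too few to say more.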
